A study of Drosophila melanogaster with 12 samples.

How the data were processed

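The series measured total RNA of salivary glands from prepupae of 2 genotypes at 12 and 14 h after pupariation, with 3 libraries in each of 4 groups. Per the labels, RNA was prepared with the NucleoSpin RNA kit and sequenced from a standard Illumina library, and animals were raised on a cornmeal molasses diet. The deposited table holds read counts per gene, made by the authors before deposition; its values are whole numbers at or above 0 with a different total in each library. The tools named per the submitters' processing notes are cutadapt 1.16, STAR 2.7.6a, featureCounts 1.6.3 and DESeq2 1.30.1, with the build BDGP6. The notes give no order or role of the tools, and the annotation release, the strand setting and the treatment of reads that map to more than 1 place are not stated. Reads were not used here.

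The table lists 17807 FlyBase genes, of which 17710 were matched to gene names and positions on the reference annotation and 97 were not matched. Genes without a match stayed in the fit under their identifiers and were not named. Some items of the fixed lists are not reported here. Counts were 0 in all libraries for 3929 genes. Positions come from the reference annotation, whose release may differ from the one the authors used. Of 242 named genes, 73 overlap exons of another gene; over 20% of exon length is shared on the same strand for 4 and on the opposite strand for 7, so their counts can include reads of a neighbour where the strand was not used.

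Total counts ran from 6977403 to 9497317 per library, so a count of 3 is 0.316 to 0.43 CPM. Genes were filtered with filterByExpr over the 4 groups, which left 7584, and libraries were scaled by TMM. A quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) was fitted to all 12 libraries with 4 group means and 8 residual degrees of freedom. The contrasts were mutant against control at 12 h and at 14 h, 14 h against 12 h in each genotype, and the difference of the genotype effects between the times. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. Replicate numbers were not used to pair libraries, since in 18 same-number pairs the correlations of deviations from the group means ran from -0.257 to 0.238.

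The 16 pathway lists were ecdysone regulators, glue genes, late 71E genes, cell death, autophagy, lysosome, salivary gland identity, secretory pathway, cytoplasmic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, proteasome, DNA replication, immune peptides, heat shock and glycolysis. The 6 marker lists were fat body, hemocyte, muscle, neuron, epidermis and trachea, and imaginal ring and disc. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the lists of a comparison. Members higher and lower in the edgeR test were counted with p adjusted over all genes and over the list alone.

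The genes to be named were chosen by a rule. It took Eip93F first, then the 8 largest rises and 8 largest falls in each genotype comparison and in the control time comparison, and 5 and 5 in the mutant time comparison and the interaction. These had to have an adjusted p under 0.05, a mean of at least 10 CPM in the higher group, a gene symbol other than a provisional or non-coding one, and, except for the interaction, no overlap between the libraries compared. It added up to 4 members of each list with the smallest p, every ecdysone regulator, for a marker list without a call the member with the highest mean, and roX1 and roX2. The text names part of the genes so chosen; mesh, Ssk and the other genes of single libraries, the family members, and late 71E and SoxN values outside the rule were chosen after their values were seen. The design, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

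Alternatives were DESeq2 1.42.0 and limma voom in place of edgeR, RLE size factors, library size alone, TMM without the 20 most abundant genes, no filter, a filter of at least 5 CPM in at least 3 libraries, a fit of the compared groups only, a replicate block over all libraries or within time, thresholds of 0.01 or of at least 2-fold, an estimated correlation in camera, and leaving out each library in turn. Another 2 were added after seeing the data, leaving out the 12 h mutant replicate 1 and the 14 h mutant replicate 2, and leaving out these and the 12 h control replicate 1.

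The steps were tested on simulated data. Counts were drawn independently for each gene, with the same spread in all groups and no change with time. The real groups differ in spread, so the simulated share of false calls need not hold for them. With 190 changed genes among 7201 in the 12 h design, 11.5% of 2-fold and 69.1% of 4-fold changes were recovered and 6.2% of calls were false. In the 14 h design, with 188 of 7184, these were 18.9%, 77.4% and 2.2%. The sign was right in 100% of the calls of changed genes.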

Results

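RNA was counted per gene in 12 libraries of salivary glands dissected from Drosophila melanogaster prepupae at 12 and 14 h after pupariation. Control animals carried 1 copy of the E93Δ1 allele, and mutant animals carried the allele pair E93Δ12/E93Δ13. Both genotypes also carried fkh>GFP, a reporter driven in the salivary gland. E93, written Eip93F here, encodes an ecdysone-induced transcription factor, and ecdysone is the steroid hormone whose pulses time metamorphosis. Each of the 4 groups held 3 libraries. Total counts per library were 8294915, 8534529 and 7588162 in the 12 h controls and 7215918, 9277965 and 6977403 in the 12 h mutants. At 14 h they were 8168194, 7889351 and 7757344 in controls and 7784303, 7655109 and 9497317 in mutants. A gene with 0 counts in a library could therefore have been present at up to 0.316 to 0.43 CPM (counts per 1e+06 counts of the library), a floor of 3 counts that covers counting error only. The labels do not say whether the replicates of a group came from separate animals or collections, so each p-value measures the spread between these samples. That spread was estimated over all 12 libraries together, not from the compared groups alone, and the groups differ in it. Replicate correlations of log2 CPM ran from 0.946 to 0.975 in 12 h controls and from 0.984 to 0.988 in 14 h controls. Below, CPM is scaled by the trimmed mean of M-values (TMM), and errors of CPM are SD with n = 3. Errors of log2 fold changes are given as SE, computed as the absolute log2 fold change over the square root of the edgeR quasi-likelihood F. They are approximate, above all where a group has few counts and the fold change depends on the prior count. The edgeR p-values were adjusted by the Benjamini-Hochberg method over 7584 genes.

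The first principal component of log2 CPM held 53.5% of the variance and separated the times, and the second held 21.2% and separated the genotypes. On the first component the 12 h control replicate 1 lay at -3.2, between the other 12 h controls (-55.2 and -62.1) and the 14 h controls (60.4 to 64.4). Correlations of log2 CPM across genes within groups ran from 0.946 to 0.988. Genes at least 4-fold above both partners numbered 104 in the 12 h mutant replicate 1, 56 in the 12 h control replicate 1, 33 in the 14 h mutant replicate 2, 17 and 13 in the 12 h mutant replicates 2 and 3, and 6 or fewer in each other library. Genes as far below both partners numbered 32 and 19 in the 12 h control replicates 1 and 3, 13 and 23 in the 12 h mutant replicates 1 and 3, and 4 or fewer in each other library. The sets of 104 and 33 shared 29 genes, against 0.19 if they were independent. Among these genes, mesh and Ssk, which encode proteins of the smooth septate junctions of gut epithelium, stood at 135.4 and 46.5 CPM in that 12 h library and at 56.7 and 31.5 CPM in that 14 h library. They stood at 12.5 and 5.2 CPM in the 12 h mutant replicate 2 and 2.8 and 3.1 CPM in the 14 h mutant replicate 3. These 2 genes were at or under 1.6 CPM in each control library.

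**Figure D1:**
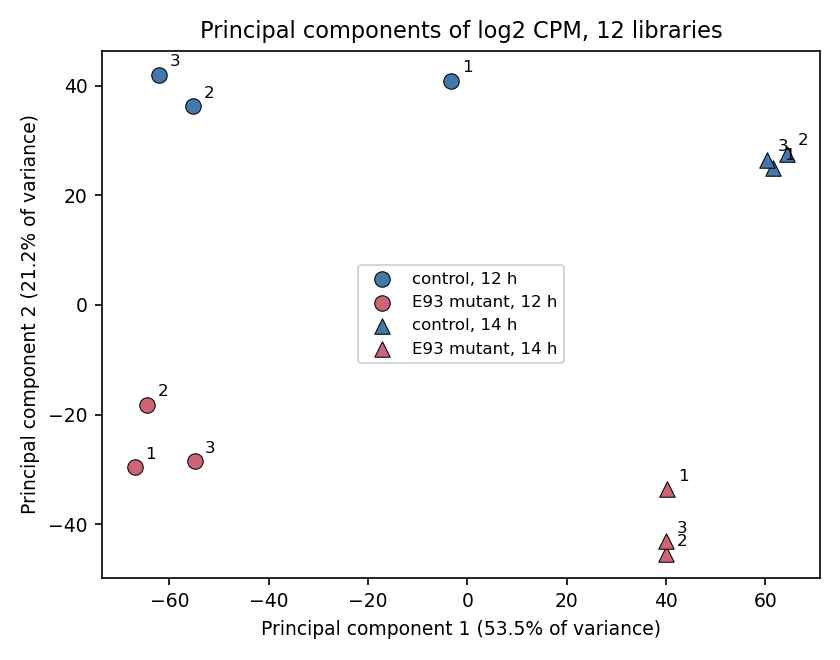
Principal components of log2 CPM for the 12 libraries, with component 1 (53.5% of the variance) on the horizontal axis and component 2 (21.2%) on the vertical axis; each point is a library, numbered by replicate. The 12 h control replicate 1 lies at -3.2 on component 1, between the other 12 h controls and the 14 h controls.

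Transcripts counted over Eip93F itself (FBgn0264490, chromosome 3R, 21949114 to 22014539, plus strand) were more abundant in the libraries labelled mutant at both times. At 12 h they stood at 4080 ± 222 CPM in mutants and 1720 ± 482 CPM in controls, a log2 fold change of 1.24 (SE 0.2, edgeR adjusted p = 0.00178). At 14 h the values were 1990 ± 32.7 and 845 ± 61.4 CPM, a log2 fold change of 1.23 (SE 0.2, edgeR adjusted p = 0.00133). Every mutant library exceeded every control library of its time. Between 12 and 14 h the level fell by 1.03 on the log2 scale in controls and by 1.04 in mutants. Counts over a whole gene do not show whether the transcripts encode working protein.

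The comparison of mutant and control glands at 12 h addressed how ecdysone-regulated expression in late prepupal glands differed between libraries labelled with the E93Δ12/E93Δ13 pair and controls. Some genes were nearly silent in mutants: Ptp52F (FBgn0034085, 2R, 16171112 to 16178307), a receptor-type protein tyrosine phosphatase, fell from 2840 ± 304 CPM in controls to 4.68 ± 3.25 CPM in mutants (log2 fold change -9.23, SE 0.63). Mgat3 (FBgn0051849, 2L, 13180398 to 13182596), a glycosyltransferase of N-glycan synthesis, fell from 1280 ± 446 to 0.812 ± 0.564 CPM (log2 fold change -10.58, SE 0.48). The diacylglycerol kinase gene Dgk (log2 fold change -5.65, SE 0.44), the heparan sulfate sulfotransferase gene Hs3st-A (-6.09, SE 0.54) and MED16 (-4.63, SE 0.19), a subunit of the Mediator complex, fell too. In the other direction, ko rose from 5.03 ± 0.665 to 256 ± 58.1 CPM (log2 fold change 5.66, SE 0.26). The zinc-finger gene sqz rose from 0.23 ± 0.218 to 112 ± 23.9 CPM (8.76, SE 0.64). Sdr, which encodes a secreted binding protein for insulin-like peptides, rose from 1.18 ± 0.852 to 44.7 ± 15.8 CPM (5.16, SE 0.4). Dop1R1, a dopamine receptor gene, had 682 counts over the 3 mutant libraries and 0 over the 3 controls, at least 240-fold higher against a floor of 3 counts over the group. All of these genes had adjusted p of 1.51e-05 or less in the edgeR test. Leaving out 1 library gave 9.43 for sqz (control replicate 2), 5.77 for Sdr (control replicate 1) and -6.4 for Dgk (mutant replicate 1).

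The ecdysone regulators were uneven at 12 h. Of 15 measured members, 4 rose and 1 fell over all genes tested, and 6 rose and 1 fell when adjusted over the list alone. Eip75B, a nuclear receptor gene, rose from 330 ± 204 to 1540 ± 233 CPM (log2 fold change 2.23, SE 0.38), and MsrA (also Eip71CD), a methionine sulfoxide reductase, rose from 47.7 ± 15 to 267 ± 31 CPM (2.48, SE 0.22). The broad-complex gene br, a zinc-finger regulator of the prepupal response, rose from 941 ± 526 to 3140 ± 378 CPM (1.74, SE 0.36). Eip74EF stood at 2840 ± 367 CPM in mutants and 1310 ± 745 in controls (1.12, SE 0.4), which did not pass the test (edgeR adjusted p = 0.0758). The list as a whole ranked higher, with a median log2 fold change of 0.32 (limma camera, adjusted p = 0.0162), and adjusted p = 0.966 with an estimated correlation. Without the 12 h control replicate 1, control replicate 2, mutant replicate 1 or mutant replicate 2 the camera p became 0.123, 0.0569, 0.0576 or 0.113. The median was 0.1 without the control replicate 1 and 0.53 without the control replicate 3.

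**Figure D2:**
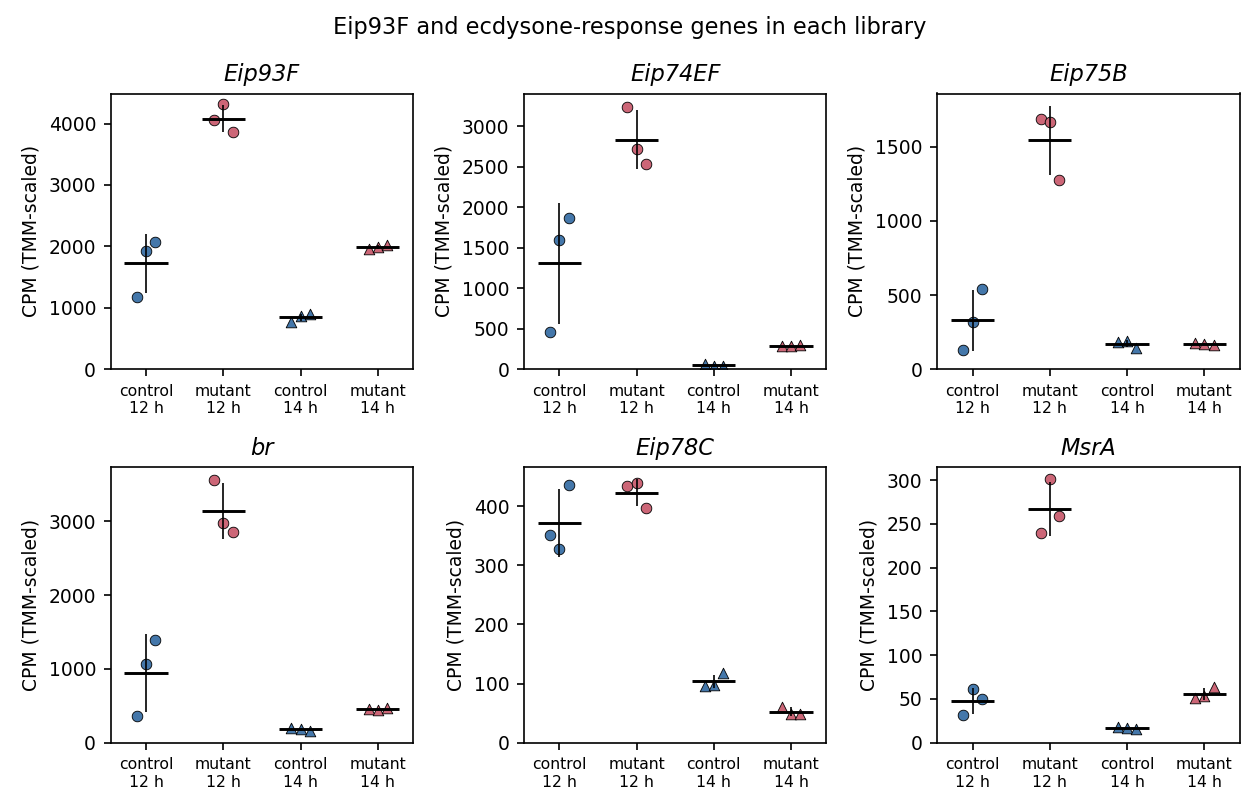
TMM-scaled CPM (vertical axes, linear and starting at 0) of Eip93F and 5 ecdysone-response genes in each library, by genotype and hours after pupariation; points are libraries, horizontal lines means and vertical lines SD (n = 3). At 12 h Eip75B stands at 1540 CPM on average in mutants and 330 in controls, and at 14 h at 171 and 173.

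The glue genes encode the secreted adhesive that fixes the puparium to its surface. Of 10 measured members 5 rose and 0 fell in 12 h mutants (6 and 0 when adjusted over the list alone), with a median log2 fold change of 1.51 (limma camera, adjusted p = 0.000419; adjusted p = 0.602 with an estimated correlation). Sgs1 rose by 2.3 on the log2 scale (SE 0.38), Sgs8 by 1.91 (SE 0.33) and Sgs5bis from 277 ± 191 to 2390 ± 1930 CPM (3.11, SE 0.62). Leaving out the 12 h mutant replicate 3 gave 2.17 for Sgs5bis, and leaving out the control replicate 3 gave 3.79. In the secretory pathway list 5 of 24 members rose (7 when adjusted over the list alone), among them gammaCOP, a coat protein of transport vesicles (0.81, SE 0.17), and the median was 0.39 (limma camera, adjusted p = 0.00205; adjusted p = 0.446 with an estimated correlation). In the salivary gland identity list 3 members rose and 1 fell of 12, and 5 rose and 2 fell when adjusted over the list alone (limma camera, adjusted p = 0.248).

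Of 12 glycolysis genes 3 rose in 12 h mutants (4 when adjusted over the list alone), including the aldolase gene Ald1 (log2 fold change 1.04, SE 0.17), with a median of 0.7 (limma camera, adjusted p = 0.00501; adjusted p = 0.817 with an estimated correlation). Among 63 oxidative phosphorylation genes 5 rose (4 when adjusted over the list alone), the largest being COX7C, a subunit of cytochrome c oxidase, at 1.51 (SE 0.21). The list's median was 0.22 (limma camera, adjusted p = 0.0131; adjusted p = 0.966 with an estimated correlation). Only 1 of 81 cytoplasmic ribosomal protein genes rose (0 when adjusted over the list alone), with a median of 0.22 (limma camera, adjusted p = 0.00205; adjusted p = 0.966 with an estimated correlation). In the lysosome list 4 of 21 genes rose (4 when adjusted over the list alone), among them the cathepsin gene cathD (0.94, SE 0.2), with a median of 0.35 (limma camera, adjusted p = 0.0417; adjusted p = 0.966 with an estimated correlation). Without the 12 h control replicate 1 the camera p was 0.123 for glycolysis (median 0.37), 0.268 for oxidative phosphorylation (0.06), 0.947 for ribosomal proteins (-0.02) and 0.457 for the lysosome (0.13). Without the mutant replicate 2 it was 0.167 for both oxidative phosphorylation and ribosomal proteins (medians 0.15 and 0.11) and 0.161 for the lysosome (0.22). Medians rose to 1.1 for glycolysis without the control replicate 3 and 0.34 for oxidative phosphorylation without the control replicate 2. The lysosome call also ended without the control replicate 2 (0.0519), the mutant replicate 1 (0.246), the 14 h control replicate 2 (0.0717) or a 14 h mutant replicate (0.0659 to 0.0679), and with relative log expression (RLE) size factors (0.053).

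Lists of cell clearance and defence did not pass as sets in 12 h mutants. In the cell death list 0 members rose and 1 fell of 16 (0 and 0 when adjusted over the list alone), and the autophagy list held 2 that rose and 1 that fell of 23 (2 and 1 when adjusted over the list alone), with limma camera adjusted p of 0.692 and 0.934. The autophagy protease gene Atg4b fell from 561 ± 106 to 289 ± 35.4 CPM (log2 fold change -0.96, SE 0.19). For immune peptides 4 of 14 rose (4 rose and 1 fell when adjusted over the list alone), with a median of -0.63 (limma camera, adjusted p = 0.934). For heat shock genes 2 of 14 rose and 1 fell, or 2 and 2 when adjusted over the list alone (limma camera, adjusted p = 0.934). The heat shock list's median of -0.04 lay below 0 and its camera direction was upward. The small heat shock gene Hsp67Bc rose from 890 ± 131 to 2260 ± 445 CPM (1.35, SE 0.2). Of the late 71E genes 1 of 10 rose (0 when adjusted over the list alone), with a median of 0.55 (limma camera, adjusted p = 0.0711). That list passed, upward, with library size alone (limma camera, adjusted p = 0.0396), no filter (0.0236), a replicate block (0.0199), or without the control replicate 2 (0.027), the control replicate 3 (0.0143) or the 14 h mutant replicate 1 (0.0232). Proteasome genes had 0 of 31 that rose and 1 that fell (0 and 0 over the list alone), with limma camera adjusted p = 0.77. DNA replication genes had 2 of 17 that rose and 1 that fell (2 and 1), with limma camera adjusted p = 0.934. Of the ribosome biogenesis genes 0 of 12 changed (0 over the list alone), with limma camera adjusted p = 0.547.

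Over all genes tested, 602 were higher and 597 lower in 12 h mutants, 490 and 351 of them by at least 2-fold. Without the 12 h mutant replicate 1 the number called was 798 in place of 1199. A fit of the 2 compared groups only called 459 and ended the calls for br, cathD and gammaCOP, and leaving out both libraries with gut-type genes, an alternative chosen after seeing the data, gave 677. Among markers of other tissues at 12 h, 0 of 8 fat body, 0 of 6 hemocyte, 0 of 8 muscle and 0 of 6 neuron markers were called (0 in each when adjusted over the list alone). In the epidermis and trachea list 1 of 8 was higher and in the imaginal ring and disc list 1 of 7 (0 and 1 when adjusted over the list alone). The limma camera adjusted p was 0.346 or more for each of these lists. The epidermis and trachea list passed, upward, without the 12 h mutant replicate 1 (median 1.04, limma camera adjusted p = 0.0383), without both libraries with gut-type genes (0.04), and without these and the control replicate 1 (median 1.69, 0.0253). The imaginal list's median of -0.39 lay below 0 and its camera direction was upward.

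**Figure D3:**
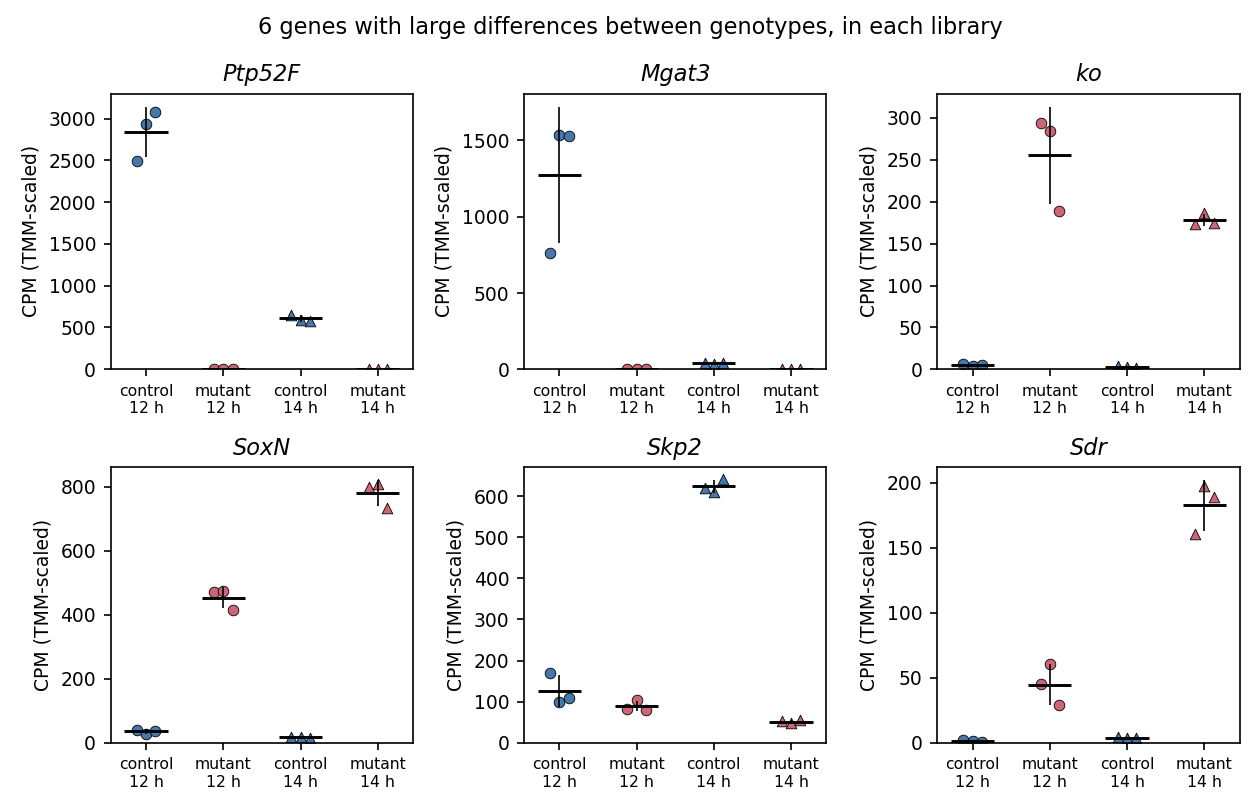
TMM-scaled CPM (vertical axes, linear and starting at 0) of 6 genes with large differences between genotypes, by genotype and hours after pupariation; points are libraries, horizontal lines means and vertical lines SD (n = 3). Ptp52F stands at 2840 CPM on average in 12 h controls and 4.68 in 12 h mutants.

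At 14 h the comparison of genotypes asked the same question later in the prepupal response. The late 71E genes, a cluster of small secreted-protein genes on 3L that ecdysone induces in the prepupal gland, were the group with the largest shift. Of 10 members 8 rose (9 when adjusted over the list alone) by 1.82 to 5.18 on the log2 scale, with edgeR adjusted p of 0.0489 or less, and the median was 3.45 (limma camera, adjusted p = 7.97e-07; adjusted p = 0.83 with an estimated correlation). Eig71Ec stood at 2860 ± 1680 CPM in mutants and 82.3 ± 18.2 in controls (log2 fold change 5.12, SE 0.57), Eig71Ed at 2940 ± 1850 and 90.8 ± 23.1 (5.02, SE 0.61), and Eig71Ef at 2800 ± 1710 and 76.9 ± 19.8 (5.18, SE 0.68). Eig71Ej (1.28, SE 0.49) and Eig71Ek (0.72, SE 0.54) did not pass the test.

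**Figure D4:**
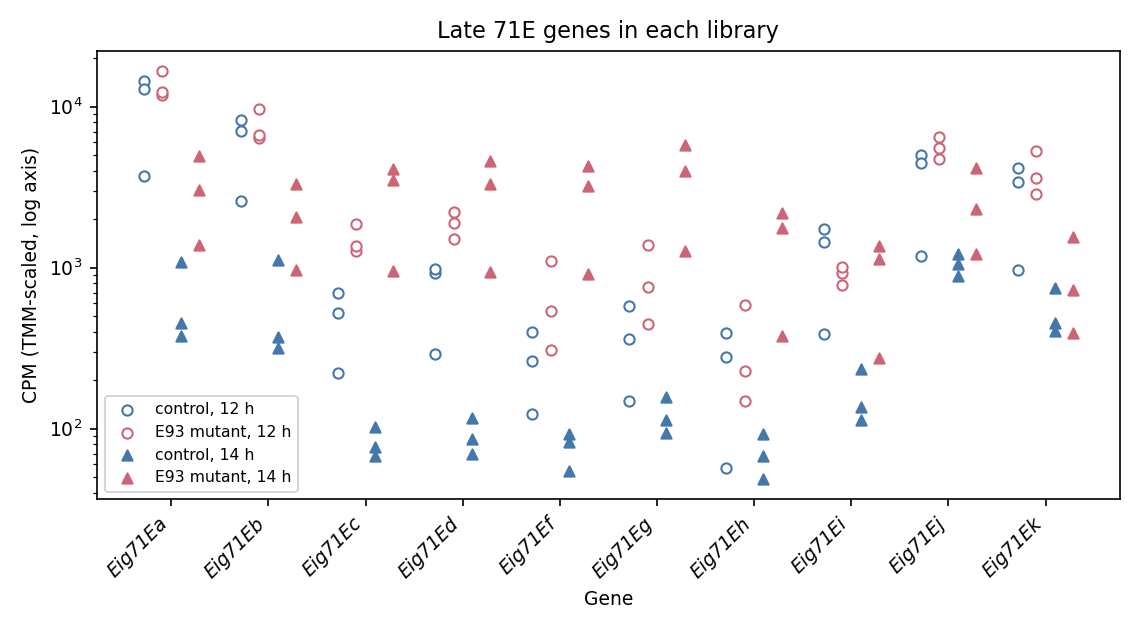
TMM-scaled CPM (vertical axis, log scale) of the 10 late 71E genes in each library; points are libraries, colour marks genotype and shape marks 12 or 14 h. For Eig71Ec the 14 h mutants average 2860 CPM and the 14 h controls 82.3.

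Other large differences at 14 h included regulators. SoxN (FBgn0029123, 2L, 8825645 to 8829670), a Sox-family transcription factor, rose from 16.7 ± 2.92 CPM in controls to 780 ± 40.8 in mutants (log2 fold change 5.55, SE 0.21). The nuclear receptor gene Hr38 rose from 2.24 ± 0.185 to 124 ± 15.9 CPM (5.78, SE 0.35) and ko from 2.83 ± 0.888 to 178 ± 7.09 CPM (5.96, SE 0.27). RluA-1 rose from 2.41 ± 0.129 to 111 ± 13.2 CPM (5.51, SE 0.2) and Sdr from 4 ± 0.314 to 182 ± 19.5 CPM (5.5, SE 0.37). Skp2 (FBgn0037236, 3R, 4334879 to 4337674), an F-box subunit of a ubiquitin ligase, fell from 624 ± 16.3 to 51.4 ± 3.9 CPM (-3.6, SE 0.22). Sema1b, a transmembrane semaphorin, fell from 723 ± 47.3 to 44.3 ± 10.9 CPM (-4.03, SE 0.44). Ptp52F fell from 608 ± 36.6 to 2.91 ± 1.9 CPM (-7.71, SE 0.6), Mgat3 from 40.1 ± 3.09 to 0.679 ± 0.128 CPM (-5.86, SE 0.42) and Dgk from 153 ± 18.6 to 3.88 ± 1.4 CPM (-5.3, SE 0.43). Each of these genes had an edgeR adjusted p of 6.34e-05 or less. Without the mutant replicate 2 the Ptp52F value was -8.35.

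Of the 15 ecdysone regulators 4 rose and 1 fell at 14 h (6 and 1 when adjusted over the list alone). The list did not shift as a set (limma camera, adjusted p = 0.408), and its median of -0.05 lay below 0 while the camera direction was upward. Eip74EF, an ETS-domain transcription factor gene, rose from 47.4 ± 15.8 to 288 ± 8.9 CPM (log2 fold change 2.6, SE 0.42), MsrA from 17 ± 1.05 to 55.7 ± 6.73 CPM (1.71, SE 0.22) and the ecdysone importer gene Oatp74D from 26.8 ± 2.51 to 68.8 ± 7.08 CPM (1.36, SE 0.21). Eip78C, a nuclear receptor gene, fell from 104 ± 11.7 to 52.8 ± 7.3 CPM (-0.97, SE 0.17). Eip75B was at 171 ± 6.81 CPM in mutants and 173 ± 24 in controls (-0.01, SE 0.36). The ecdysone receptor gene EcR was at 162 ± 18.4 and 190 ± 18.6 CPM (-0.23, SE 0.26, edgeR adjusted p = 0.641).

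Of the glue genes 4 of 10 rose and 0 fell at 14 h (4 and 0 when adjusted over the list alone), with a median of 1.32 (limma camera, adjusted p = 0.00785; adjusted p = 0.83 with an estimated correlation). The median was 0.8 without the 14 h control replicate 1. Sgs5bis stood at 819 ± 330 CPM in mutants and 45.7 ± 16 in controls (log2 fold change 4.16, SE 0.65). Among cell death genes 1 rose and 2 fell of 16 (1 and 2 when adjusted over the list alone; limma camera, adjusted p = 0.633). The engulfment receptor gene drpr fell from 448 ± 27.8 to 144 ± 43.6 CPM (-1.64, SE 0.27), and Buffy, a Bcl-2 family gene, rose from 72.8 ± 11.8 to 158 ± 13.7 CPM (1.12, SE 0.23). In the lysosome list 2 rose and 1 fell of 21 (2 and 1 when adjusted over the list alone), with limma camera adjusted p = 0.115. Vha100-2, a subunit of the proton pump, rose from 39.9 ± 1.56 to 223 ± 30.1 CPM (2.48, SE 0.24). In the autophagy list 2 of 23 rose (0 when adjusted over the list alone) and in the salivary gland identity list 1 of 12 (1 over the list alone), both with limma camera adjusted p = 0.782. The proteasome and DNA replication lists had 0 called (0 over each list alone), with limma camera adjusted p of 0.177 and 0.782, and 0.0335 for the proteasome without the 14 h mutant replicate 1.

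Immune peptide genes rose in part at 14 h, with 4 of 14 higher and 0 lower (5 and 1 when adjusted over the list alone), among them Mtk from 0.247 ± 0.226 to 4.72 ± 1.11 CPM (log2 fold change 4.19, SE 0.61) and Drs from 7.25 ± 1.94 to 36.3 ± 11.1 CPM (2.32, SE 0.51). The list's camera p was 0.317, with a median of -0.06 below 0 and an upward direction. Without the 14 h control replicate 3 the Mtk value was 4.82. A further 6 lists ranked higher with limma camera adjusted p between 0.0368 and 0.0496, and with 0.83 or more with an estimated correlation. The limma camera adjusted p was 0.0368 for the secretory pathway, where 2 of 24 rose (0 over the list alone, median 0.39). For glycolysis 3 of 12 rose (3, median 0.415) and for ribosomal proteins 0 of 81 (0, median 0.18), both with limma camera adjusted p = 0.0412. Ribosome biogenesis had 0 of 12 (0, median 0.76), with limma camera adjusted p = 0.0457. Oxidative phosphorylation had 2 of 63 (1, median 0.22), with limma camera adjusted p = 0.0471. Heat shock had 3 of 14 (3, median 0.7), with limma camera adjusted p = 0.0496. The hexokinase gene Hex-A rose from 3.81 ± 0.916 to 41.9 ± 6.76 CPM (3.45, SE 0.36), COX7C from 31.1 ± 4.42 to 133 ± 28.3 CPM (2.1, SE 0.21) and Hsp26 from 31.2 ± 1.96 to 83.1 ± 18.1 CPM (1.42, SE 0.25). Each of those 6 camera calls ended without at least 1 library. Without the 14 h mutant replicate 3 the p was 0.0542 for the secretory pathway, 0.291 for ribosomal proteins (median 0.1) and 0.285 for oxidative phosphorylation (0.11). Without the mutant replicate 2 it was 0.168 for heat shock (median 0.18) and 0.0711 for glycolysis (0.26), and without the mutant replicate 1 it was 0.214 for ribosome biogenesis. Without the control replicate 2 it was 0.0636, 0.21, 0.188, 0.114 and 0.0533 for the secretory, ribosomal protein, oxidative phosphorylation, heat shock and ribosome biogenesis lists. Without the control replicate 3 it was 0.0992 for glycolysis (median 0.17). Other single libraries ended the glycolysis, ribosomal protein, ribosome biogenesis, oxidative phosphorylation and heat shock calls too (limma camera adjusted p of 0.0534 to 0.173). The heat shock call also ended with RLE size factors (0.058), library size alone (0.0548), a filter of at least 5 CPM (0.104) or a replicate block (0.0506). RLE size factors ended the calls for oxidative phosphorylation (0.0749) and ribosomal proteins (0.0783), library size alone those for oxidative phosphorylation (0.0548) and ribosome biogenesis (0.0552), and no filter that for oxidative phosphorylation (0.0566).

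In all, 629 genes were higher and 524 lower in 14 h mutants, 515 and 324 of them by at least 2-fold. In place of 1153 calls there were 745, 701 and 767 without the control replicates 1, 2 and 3 at 14 h. There were 1586 without the 12 h control replicate 1, and 2128 in a fit of the 2 compared groups only. Markers of other tissues were called singly. They were 1 of 8 fat body markers higher (1 over the list alone), 1 of 6 hemocyte markers lower (1), 1 of 6 neuron markers higher (1), 1 of 8 epidermis and trachea markers higher (0), 1 of 7 imaginal markers higher (1) and 0 of 8 muscle markers (0), with limma camera adjusted p of 0.197 or more for each list.

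The genotype effects at the 2 times shared genes and directions, in comparisons with no library in common. Higher at both times were 273 genes against 49.9 if the calls were independent, and lower at both were 232 against 41.2. Only 6 and 10 genes were called in opposite directions. Ptp52F, Mgat3 and Dgk were among the genes lower at both times, and ko, sqz, Sdr and SoxN (log2 fold change at 12 h 3.68) among those higher at both. Across the 7584 genes tested, which are not independent replicates, Pearson's r between the log2 fold changes was 0.644 and Spearman's rho 0.548.

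**Figure D5:**
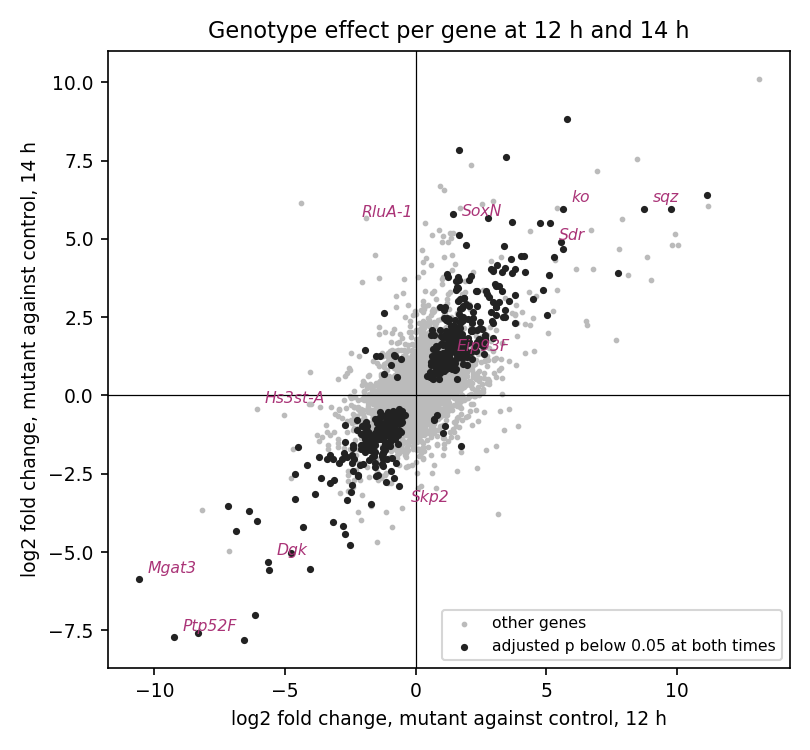
Log2 fold change of mutants against controls per gene at 12 h (horizontal axis) and 14 h (vertical axis); each point is 1 of 7584 genes, dark where the adjusted p was below 0.05 at both times. Ptp52F (-9.23 and -7.71) lies at the lower left and ko (5.66 and 5.96) at the upper right; fitted values of genes with 0 counts in a group depend on the prior count.

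The change from 12 to 14 h in control glands gives the course that the mutant glands are set against. Of the 15 ecdysone regulators 10 fell and 2 rose (11 and 2 when adjusted over the list alone), with a median of -1.08 (limma camera, adjusted p = 0.0032; adjusted p = 0.525 with an estimated correlation). Eip74EF fell from 1310 ± 745 to 47.4 ± 15.8 CPM (log2 fold change -4.78, SE 0.46), the nuclear receptor gene Hr4 from 575 ± 280 to 44.2 ± 5.43 CPM (-3.7, SE 0.35). The br level fell from 941 ± 526 to 184 ± 20.7 CPM (-2.36, SE 0.37). EcR rose from 55 ± 22.8 to 190 ± 18.6 CPM (1.79, SE 0.27) and Eip63E, a cyclin-dependent kinase gene, from 235 ± 127 to 1410 ± 103 CPM (2.58, SE 0.33). Of the 10 late 71E genes 9 fell (10 when adjusted over the list alone), with a median of -2.47 (limma camera, adjusted p = 0.00171; adjusted p = 0.525 with an estimated correlation). Eig71Ea fell from 10300 ± 5810 to 639 ± 390 CPM (-4.02, SE 0.62), and the value was -4.64 without the 14 h control replicate 3. Glue genes fell in 5 of 10 cases (5 when adjusted over the list alone), with a median of -1.16 (limma camera, adjusted p = 0.0309; adjusted p = 0.525 with an estimated correlation). That call ended without the 12 h control replicate 2 (0.077, median -0.72) or 3 (0.0552), and with a filter of at least 5 CPM (0.0639).

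Of 81 ribosomal protein genes 77 fell in controls (77 when adjusted over the list alone), with a median of -0.88 (limma camera, adjusted p = 1.01e-16; adjusted p = 0.525 with an estimated correlation). Of 12 glycolysis genes 8 fell (8 over the list alone; limma camera, adjusted p = 0.00081; adjusted p = 0.525 with an estimated correlation). They included Ldh, from 113 ± 46.8 to 3.9 ± 1.34 CPM (log2 fold change -4.85, SE 0.39), and Gapdh2, from 81.5 ± 33.1 to 15.2 ± 0.615 CPM (-2.42, SE 0.29). Proteasome genes rose in 15 of 31 cases (16 when adjusted over the list alone), with a median of 0.57 (limma camera, adjusted p = 0.00171; adjusted p = 0.525 with an estimated correlation). The lid gene Rpn11 rose from 20.1 ± 4.29 to 46.8 ± 1.97 CPM (1.22, SE 0.17). Heat shock genes fell in 8 of 14 cases and rose in 1 (8 and 1 over the list alone), with a median of -1.76 (limma camera, adjusted p = 0.0187; adjusted p = 0.525 with an estimated correlation). With a filter of at least 5 CPM the heat shock call ended (median -0.73, limma camera adjusted p = 0.0985). The chaperone gene DnaJ-1 fell from 256 ± 134 to 16.1 ± 3.21 CPM (-3.99, SE 0.43).

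Of the cell death genes 10 fell and 4 rose of 16 in controls (10 and 4 over the list alone), with a median of -0.71 (limma camera, adjusted p = 0.0317; adjusted p = 0.525 with an estimated correlation). Of the autophagy genes 9 fell and 2 rose of 23 (9 and 2), with a median of -0.4 (limma camera, adjusted p = 0.0187; adjusted p = 0.525 with an estimated correlation). Of the lysosome genes 10 fell and 2 rose of 21 (11 and 3), with a median of -0.68 (limma camera, adjusted p = 0.0187; adjusted p = 0.525 with an estimated correlation). Buffy fell from 529 ± 160 to 72.8 ± 11.8 CPM (-2.86, SE 0.24), the caspase gene Strica from 700 ± 257 to 117 ± 2.08 CPM (-2.58, SE 0.25). Atg13 fell from 1030 ± 171 to 286 ± 12.2 CPM (-1.85, SE 0.18) and the cathepsin gene CtsL1 from 28300 ± 823 to 11800 ± 219 CPM (-1.27, SE 0.19). The cell death call ended without any 1 of the 12 h controls 1, 2 and 3 (0.0756, 0.0576, 0.0552), the 12 h mutants 2 and 3 (0.0555, 0.0621) or the 14 h mutants 1 and 3 (0.0513, 0.0523), and the lysosome call without the 12 h control replicate 3 (0.0552). A filter of at least 5 CPM ended the calls for cell death (limma camera adjusted p = 0.073), autophagy (0.0643) and the lysosome (0.0643), and without a filter the cell death median was -0.26.

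Fat body markers rose in controls in 4 of 8 cases (5 when adjusted over the list alone), with a median of 1.12 (limma camera, adjusted p = 0.0187; adjusted p = 0.525 with an estimated correlation). The lipoprotein gene apolpp rose from 27 ± 5.89 to 84.4 ± 12.1 CPM (log2 fold change 1.65, SE 0.25). Hemocyte markers rose in 3 of 6 cases, muscle markers fell in 3 of 8 and neuron markers rose in 1 of 6, with limma camera adjusted p of 0.109, 0.0651 and 0.171. Muscle markers passed without the 12 h control replicate 1 (0.0371), 12 h mutant replicates 1 or 2 (0.0412, 0.0484) or the 14 h control replicate 1 (0.0487), and with library size alone (0.0233), no filter (0.0463) or a replicate block (0.0398). Epidermis and trachea markers fell in 3 and rose in 1 of 8, and imaginal markers fell in 1 of 7, with limma camera adjusted p of 0.253 and 0.569. The remaining lists in controls gave limma camera adjusted p of 0.109 for oxidative phosphorylation (3 rose and 8 fell of 63; 0.0334 without the 12 h control replicate 1), 0.201 for immune peptides (4 rose and 1 fell of 14), 0.469 for DNA replication and 0.659 for the secretory pathway. Both ribosome biogenesis and gland identity had 0.86, and their medians of -0.02 and -0.1 lay below 0 with an upward camera direction. The antimicrobial gene Dro rose from 88.9 ± 145 to 1550 ± 143 CPM (4.12, SE 1.27). It stood at 256.78 CPM in the 12 h control replicate 1 and 3.61 and 6.4 in the others, and its value without that library was 8.22. Thor, which encodes the translation inhibitor 4E-BP, fell from 6580 ± 4610 to 117 ± 72.4 CPM (-5.82, SE 0.73), or -6.46 without the 14 h control replicate 1. The kinase gene Cdc7 fell from 172 ± 110 to 3.72 ± 0.527 CPM (-5.53, SE 0.62).

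Over all genes, 1575 rose and 1702 fell in controls from 12 to 14 h. TMM factors ran from 0.753 to 0.942 at 12 h and from 1.126 to 1.261 at 14 h, so scaling by library size alone moved the median log2 change of all genes from 0.124 to 0.639 and the calls to 3042 higher and 1054 lower. Changes with time are therefore relative to the bulk of genes. With that scaling the camera p was 0.177 for autophagy (median 0.14) and 0.129 for the lysosome.

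In mutant glands over the same interval, 3 of the 10 late 71E genes rose and 3 fell (3 and 3 when adjusted over the list alone). The median was 0.34 with a downward camera direction (limma camera, adjusted p = 0.75). Eig71Ea fell by 2.11 on the log2 scale (SE 0.57), and Eig71Ef and Eig71Eg rose by 2.11 (SE 0.59) and 2.08 (SE 0.59), but these 2 calls ended without the 12 h mutant replicate 3 (edgeR adjusted p of 0.0503 and 0.0545) or the 14 h mutant replicate 3 (0.0515 and 0.0572). The ecdysone regulators fell in 12 of 15 cases and rose in 3 (12 and 3 when adjusted over the list alone), with a median of -1.75 (limma camera, adjusted p = 0.000428; adjusted p = 0.499 with an estimated correlation), or -0.94 with no filter. Eip75B fell from 1540 ± 233 to 171 ± 6.81 CPM (log2 fold change -3.17, SE 0.39) and Eip78C from 423 ± 23.2 to 52.8 ± 7.3 CPM (-3, SE 0.18). RluA-1 rose from 0.935 ± 0.205 to 111 ± 13.2 CPM (6.87, SE 0.23), D, a Sox-family gene, from 11.6 ± 2.87 to 828 ± 38.8 CPM (6.16, SE 0.39) and the eclosion hormone gene Eh from 0.524 ± 0.263 to 37.1 ± 12 CPM (6.13, SE 0.55).

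Ribosomal protein genes fell in mutants in 77 of 81 cases (78 over the list alone), with a median of -0.92 (limma camera, adjusted p = 2.11e-18; adjusted p = 0.499 with an estimated correlation). Glycolysis genes fell in 10 and rose in 1 of 12 cases (10 and 1 over the list alone), with a median of -1.33 (limma camera, adjusted p = 0.00028; adjusted p = 0.499 with an estimated correlation). Proteasome genes rose in 21 and fell in 1 of 31 cases (21 and 1), with a median of 0.79 (limma camera, adjusted p = 2.63e-05; adjusted p = 0.499 with an estimated correlation). Autophagy genes fell in 11 and rose in 2 of 23 cases (11 and 2; limma camera, adjusted p = 0.00728; adjusted p = 0.499 with an estimated correlation). Cell death genes fell in 8 and rose in 4 of 16 cases (8 and 4), with a median of -0.56 (limma camera, adjusted p = 0.0272; adjusted p = 0.499 with an estimated correlation). Fat body markers rose in 7 of 8 cases (7), with a median of 1.41 (limma camera, adjusted p = 0.0111; adjusted p = 0.499 with an estimated correlation). Immune peptide genes rose in 7 of 14 cases (9 over the list alone), with a median of 1.14 (limma camera, adjusted p = 0.022; adjusted p = 0.499 with an estimated correlation), among them Dro from 14.2 ± 14.8 to 1170 ± 313 CPM (log2 fold change 6.35, SE 1.42). Without the 12 h mutant replicate 2 the Dro value was 7.63. Lysosome genes fell in 13 of 21 cases and rose in 2 (13 and 2), with limma camera adjusted p = 0.0111. Glue genes fell in 6 and rose in 1 of 10 cases (7 and 1), with a median of -1.48 (limma camera, adjusted p = 0.0299). Both lists had adjusted p = 0.502 with an estimated correlation. Heat shock genes fell in 5 of 14 cases and rose in 1 (5 and 1), with limma camera adjusted p = 0.159. The limma camera adjusted p was 0.083 or more for each of the remaining lists in mutants. Without the 12 h mutant replicate 1 it was 0.0285 for oxidative phosphorylation, 0.0285 for epidermis and trachea, 0.0309 for hemocyte and 0.0497 for neuron markers. For oxidative phosphorylation it was also 0.0418 without the 12 h control replicate 2 and 0.0255 without the 14 h mutant replicate 3, 0.0399 with RLE size factors and 0.0405 with no filter. No filter gave 0.0392 for heat shock and 0.0266 for epidermis and trachea. A filter of at least 5 CPM ended the calls for glue genes (limma camera adjusted p = 0.0823), cell death (0.0675) and immune peptides (0.0693). The glue call ended without the 12 h mutant replicate 3 (0.0709) and the cell death call without the 12 h mutant replicate 2 (0.051), while leaving out 1 library gave cell death medians as low as -1.2 (without replicate 3).

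In mutants 1715 genes rose and 1702 fell from 12 to 14 h, or 3109 and 1038 with scaling by library size alone, which moved the median of all genes from 0.141 to 0.651. With that scaling the camera p was 0.119 for autophagy, 0.116 for the lysosome and 0.0637 for immune peptides. Of the genes called in controls, 1088 rose in both genotypes against 356.2 if the calls were independent, 1335 fell in both against 382, and 15 and 36 were called in opposite directions. Across the 3277 genes called in controls, the mutant change had a slope of 0.81 on the control change, and 0.678 without the 12 h control replicate 1. Across the 3417 genes called in mutants the same slope was 0.959. The slope depends on which call selects the genes, so 0.81 alone does not show a weaker change in mutants.

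Whether the genotype effect itself differed between 12 and 14 h was tested with an interaction term. Differences were found for Eh, at 37.1 ± 12 CPM in 14 h mutants and 1.62 ± 0.684 CPM or less on average in the other groups (log2 difference 6.05, SE 0.77), and for RluA-1 (5.17, SE 0.39), which were higher in mutants at 14 h. Hs3st-A was lower in mutants at 12 h (log2 fold change -6.09) and stood at -0.43 at 14 h (log2 difference 5.65, SE 0.67). Skp2 was at 89.2 ± 13.1 CPM in mutants and 126 ± 38.5 in controls at 12 h, and at 51.4 ± 3.9 and 624 ± 16.3 CPM at 14 h (log2 difference -3.1, SE 0.29). The glutamine synthetase gene Gs2 (-3.74, SE 0.43) and Evi5 (-3.11, SE 0.29) had differences of the same direction. The late 71E genes had a median difference of 3.19, with 4 of 10 members called and 7 when adjusted over the list alone (limma camera, adjusted p = 3.89e-05; adjusted p = 0.958 with an estimated correlation). Each of the 4 calls over all genes ended without the 14 h control replicate 2. For Eip93F the difference was -0.01 (SE 0.29, edgeR adjusted p = 0.998).

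In total 206 genes passed the edgeR test for an interaction, 133 with a higher and 73 with a lower effect at 14 h. The value for Eh was 5.31 without the 12 h control replicate 2. The number called was 430 without the 12 h control replicate 1, 105, 109 and 129 without the 14 h control replicates 1, 2 and 3, and 121 and 133 without the 14 h mutant replicates 2 and 3. The limma camera adjusted p for the interaction was 0.124 or more for every other fixed list. It was under the threshold without 1 library for heat shock (0.0111, 12 h control replicate 1) and ecdysone regulators (0.0219, 12 h control replicate 3). Muscle markers had 0.0137, 0.0225 and 0.022 (without the 12 h control replicate 1, 12 h mutant replicate 2 or 14 h mutant replicate 3). Proteasome genes had 0.00883, 0.0434 and 0.00884 (without the 12 h control replicate 3, 12 h mutant replicate 1 or 14 h mutant replicate 1). Ribosomal proteins had 0.034, 0.0266 and 0.0434 (without the 12 h control replicate 2 or 3 or the 12 h mutant replicate 1).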

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

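The tests of stage, of the 12 h control replicate 1, and of gut and fat body carry-over were chosen after the results were seen, as were the alternatives that leave out 2 or 3 libraries, while the tests of linked background, of the share of males and of other splits were planned.

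For 27 named genes the genotype effect differed between 12 and 14 h in the edgeR interaction test, and the late 71E list passed limma camera for the interaction (adjusted p = 3.89e-05; adjusted p = 0.958 with an estimated correlation). The log2 difference (14 h effect less 12 h effect) was 6.05 for Eh, 5.65 for Hs3st-A, 5.18 for ec, 5.17 for RluA-1, 4.72 for Mgat3, 4.38 for Sobp and 4.34 for Hr38. It was 3.87 for Eig71Ef, 3.67 for Eig71Ed, 3.66 for Eig71Eg, 3.47 for Eig71Ec and 1.75 for Eig71Ee, and the late 71E list had a median of 3.19. The Sox genes D, Sox21b and SoxN had 2.63, 1.99 and 1.87, and MED16, Vha100-2 and Hsp26 had 2.13, 1.99 and 1.43. Differences below 0 were -1.16 for Eip78C, -1.5 for Sugb, -1.92 for drpr, -2.24 for Eip75B, -3.1 for Skp2, -3.11 for Evi5, -3.34 for sty, -3.74 for Gs2 and -6.93 for Sk1. Leaving out 1 library gave 5.31 for Eh (12 h control replicate 2), 4.03 for ec (12 h control replicate 1) and 4.5 for Eig71Ef (12 h mutant replicate 2). For Sk1 it gave -8.82, -3.93 and -7.53 (12 h control replicate 1, 12 h mutant replicates 1 and 3). Some calls ended without 1 library, with the highest edgeR adjusted p without the 14 h control replicate 2 for Eig71Ec (0.0742), Eig71Ed (0.0791), Eig71Ef (0.0983), Eig71Eg (0.122) and Hsp26 (0.149). For Eig71Ee it was 0.0729 without the 14 h control replicate 1, for drpr 0.0582 without the 14 h mutant replicate 3 and for Sk1 0.268 without the 12 h mutant replicate 1 (edgeR adjusted p). For Eip78C and Eip75B it was 0.0702 and 0.123 without the 12 h control replicate 2 (edgeR adjusted p), and other libraries ended these calls too.

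Members of the fixed lists with too few counts to be tested reached, in a mutant library, at least 1 CPM and 4 times the level of every control library in 7 cases. In the 12 h mutant replicate 1 these were Damm (27.1 CPM), nub (13.3 CPM), Decay (12.7 CPM) and btl (5.8 CPM). The others were ng1 (5 CPM, 12 h mutant replicate 3) and, in the 14 h mutant replicate 3, DptA (1.9 CPM) and He (1.3 CPM). No control library was above 0.52 CPM for any of the 7 genes. Damm, nub and Decay also stood at 8.4, 3.5 and 3.8 CPM in the 14 h mutant replicate 2, the other library in which mesh and Ssk were high.

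Other splits of the libraries were counted for each comparison. The real split called 1199 genes for genotype at 12 h (highest other 9), 1153 at 14 h (highest other 0), 3277 for time in controls (highest other 0) and 3417 for time in mutants (highest other 0). In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the interaction, 2 of 100 drawn splits gave as many genes as the real 206, and the highest other had 261. That split exchanged replicates 2 and 3 of control and mutant at 12 h and kept the 14 h labels. Splits that keep the labels of 1 time carry the genotype effect into the contrast, so these counts do not say whether chance gives the interaction.

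The first pattern weighed is the 505 genes called for genotype at both times in the same direction. For genes that change in 1 direction over the 12 to 14 h window, a difference in stage within it would leave mutants between the controls of the 2 times. Yet 419 of the 7584 genes tested had all 6 mutant libraries on one side of all 6 control libraries (269 of them among the 505). A random order of the libraries gives 16.4 of all genes tested. Libraries of a group resemble each other, however, so 16.4 is not the number that differing groups, or a difference in stage, would give. Genes that peak or dip inside the window are not covered. For the 236 of the 505 genes without such a separation, the share with both mutant means on one side of both control means was 51.7%. A part in stage stays open, as are stages outside the window. On the first principal component the 14 h mutants lay at 40 to 40.3, short of the 14 h controls (60.4 to 64.4). Background linked to the E93 alleles may account for some calls. Genes within 5 Mb of Eip93F on 3R were called more often than those on X, 2L and 2R (54 of 643 and 248 of 4118). The odds ratio was 1.43 (95% interval 1.03 to 1.95, Fisher exact p = 0.0292), an excess of 15.3 genes in that window. On 3L, the other arm of the same chromosome, 128 of 1522 genes (8.41%) were called, as high as the 8.4% near Eip93F. A share that high is therefore not particular to the window. Over all of 3R, window included, the share was 6.91%, below that of the window. Calls on 3R were thus denser near the gene than on the rest of the arm, so that arm does not show an even rise along its length. Background on 3L or on parts of 3R was not tested and stays open. The share was 4.52% on X, 7.51% on 2L and 5.96% on 2R. A different share of males cannot be told apart. For roX1 the log2 fold change was -1.2 at 12 h (SE 0.48, edgeR adjusted p = 0.112) and 0.29 at 14 h (SE 0.48). For roX2 it was -0.91 at 12 h (SE 0.39, edgeR adjusted p = 0.143) and 0.31 at 14 h (SE 0.41, edgeR adjusted p = 0.7). At 12 h every mutant library lay below every control library for both genes (at most 72.9 against at least 81.8 CPM for roX1, 25.1 against 28.4 CPM for roX2). At 14 h the ranges overlapped. Mean levels of both also differed between the times in controls (102 and 39.1 CPM for roX1, 33.3 and 7.45 CPM for roX2). Whether the share of males differed between those collections is not known, so that difference does not decide the question. The genotype itself stays open as the biological explanation.

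The second pattern is the 12 h control replicate 1, which lay between the times. A mixture with 14 h control glands would need the same share for all genes, but the median position between the times (0 the other 12 h controls, 1 the 14 h controls) was 0.21 for 247 rising genes and 0.56 for 524 falling genes, a difference of 0.35. A 14 h library under a 12 h label is argued against by a median position of 0.41, and lower depth by a total of 8.29 (in units of 1e+06 counts) and 10075 genes with a count. Glands somewhat later in the course than their partners may remain, as no value in the tables excludes an intermediate stage, and no biological explanation was tested.

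The third pattern is the set of 104 genes far higher in the 12 h mutant replicate 1 than in its partners. Fat body carried over had 0 of 7 detected markers at least 4-fold above every 12 h control (0%), but only 1 of the 7 was under 5 CPM in controls, so a small share cannot be told apart. Gut carried over could explain genes such as mesh and Ssk and stays open too: 1 of 5 detected genes of a gut list (20%) passed the same bound, but 3 of the 5 were above 5 CPM in control glands, which would hide a small share, and the digestive enzyme genes betaTry and Amy-p were at 0.16 and 0 CPM in that library. Of these 104 genes 55 were tested and 18 called at 12 h, and leaving out this library and the 14 h mutant replicate 2 gave 677 calls. The library and its partners share 1 label of genotype and time, so genotype alone does not give the difference between them. Whether genotype has a part in the pattern, which 1 or 2 of 3 mutant libraries show, was not tested.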

How the results depend on the processing

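Leaving out 2 or 3 libraries was an alternative chosen after seeing the data. Numbers of genes called for time stayed within 1.5 times under every alternative run. For genotype at 12 h the number was 1199, against 459 in a fit of the compared groups only, 520 at an adjusted p under 0.01, 677 without both libraries with gut genes and 792 without these and the 12 h control replicate 1. Leaving out each library gave 798 (without the 12 h mutant replicate 1) to 1186. For genotype at 14 h it was 1153, against 2128 for the compared groups only, 636 at 0.01 and 701 to 1586 without 1 library. The interaction count of 206 became 333 with DESeq2, 70 with a replicate block within time, 71 at 0.01, 84 without both libraries with gut genes and 105 to 430 without 1 library. A stricter threshold lowers these counts by construction, and fewer libraries tend to lower them. The cause of the other moves was not tested, among them the rises to 2128 and 1586 for genotype at 14 h and to 333 and 430 for the interaction. The 1586 came without the 12 h control replicate 1, which is in neither 14 h group. Its removal can reach that count only through what the fit shares over all libraries: the estimate of spread, the filter and the scaling.

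The correlation of genotype effects (0.644) was 0.339 with no filter, where genes with few counts enter, 0.514 without the 3 libraries and 0.55 to 0.666 without 1 library. The slope of time effects among genes called in controls (0.81) was 0.684 without the 3 libraries and 0.678 to 0.817 without 1. The median of cytoplasmic ribosomal proteins at 12 h, 0.22, ran from -0.02 (without the 12 h control replicate 1) to 0.33. With library size alone the sign changed for Hr39 (0.02 in controls, 0.03 in mutants) and vri (0.01 in controls) over time, as that scaling moves all genes upward. A replicate block gave 1041, 1103, 3153, 3322 and 158 genes in the order of the comparisons.

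Over all alternatives, list results kept their side of the threshold in 2111 cases, lost the call in 135, gained it in 48 and, for a called list, changed camera direction in 1. The cases that kept their side include lists called neither way. Of the 135 lost calls, 37 were lost with an estimated correlation. Under that setting no fixed list passed in any comparison (limma camera adjusted p of 0.446 or more). With library size alone the autophagy median over time also changed sign (0.14 in controls, 0.08 in mutants). Named genes kept their side in 11338 cases, lost the call in 731, gained it in 170 and changed sign in 3. In the simulated 12 h design, with 190 of 7201 genes changed, 11.5% of 2-fold changes were recovered, so changes of that size can be missed. The real 12 h genotype comparison called 15.8% of the genes tested. The p needed for a call depends on how many genes change, so how often such changes are missed in the real data was not measured. The simulation gave all groups the same spread, so the share of false calls in the real data was not measured either.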

Other observations

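The tests of 51 gene families were chosen after the results were seen. Families were formed by the letters that open the symbol, with at least 8 members tested, so a set such as Su need not hold related genes. The Sox genes were the exception: they were picked by hand once SoxN and D were seen, so their set test is not given. In 14 h mutants 3 of 6 Sox genes rose, SoxN by 5.55 on the log2 scale (SE 0.21), D by 3.34 (SE 0.34) and Sox21b by 2.02 (SE 0.24). In controls 15 of 35 eIF genes fell from 12 to 14 h and 2 rose (limma camera, adjusted p = 0.00782), 6 of 15 mitochondrially encoded genes fell (0.00699) and 8 of 15 Usp genes rose and 2 fell (0.031), each with adjusted p = 0.779 with an estimated correlation. The same families passed in mutants, with 17 eIF genes lower and 3 higher (limma camera, adjusted p = 0.0184), 8 mitochondrial genes lower (0.00356) and 9 Usp genes higher and 1 lower (0.027), each with adjusted p = 0.703 with an estimated correlation. In mutants 12 of 24 Mediator genes rose over time and 1 fell (limma camera, adjusted p = 0.0216; adjusted p = 0.703 with an estimated correlation). In controls 10 rose and 2 fell (limma camera, adjusted p = 0.178), and the interaction did not pass (0.797), so a difference between genotypes is not shown. At 12 h 2 of 14 Taf genes fell in mutants (limma camera, adjusted p = 0.0399; adjusted p = 0.601 with an estimated correlation). Over time in mutants 6 of 12 Prp genes and 7 of 12 Su genes rose and 0 fell, both with limma camera adjusted p = 0.027 (adjusted p = 0.703 with an estimated correlation). In controls 4 Prp genes rose and 1 fell, and 5 Su genes rose and 0 fell (limma camera, adjusted p of 0.178 and 0.0606). The interaction did not pass for either set (limma camera, adjusted p of 0.797 and 0.956). Other families that passed, such as RpL, RpS, Rpn, Vha, COX, Atg and Eig, share members with the fixed lists.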
